A study of Mus musculus with 122 samples.

How the data were processed

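RNA was measured by 3′ polyA sequencing with MARS-seq primers in 99 libraries of cells sorted by FACS, open chromatin by ATAC sequencing in 5 cultures, and C/EBPβ binding by ChIPmentation in 2 samples of wild-type alveolar macrophages, per the labels' protocols. The series lists 122 samples. Of these, 14 further ATAC samples and 2 ChIP inputs were not analysed here. Groups were taken from the sample titles and source names, which gave 39 groups.

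The 3 deposited count tables held whole counts per Ensembl gene, for which STAR 2.6.1a and featureCounts 1.6.3 with the build GRCm38 are listed per the submitters' processing notes. Whether molecule barcodes were collapsed is not given in the sources used here, so counts are read counts or molecule counts. Each table held 22050 genes, of which 20518 matched a RefSeq symbol, 756 a RefSeq synonym and 776 neither, and 27 symbols stood for more than 1 Ensembl gene. Genes were kept as separate Ensembl entries. The peak lists gave for each peak a −log10 p and a −log10 q of the authors' peak caller, and BWA 0.7.17, Bowtie2 and MACS2 2.2.7.1 are among the tools listed per the submitters' processing notes. The score of a peak in the deposited lists was 10 times its −log10 q, whole part. The ratio given per peak was the fold over the local background, as deposited by the authors. ATAC lists held every peak number, with a lowest −log10 q of 1.34 to 1.42 per list. ChIP lists skipped numbers and began at 5 and 5.02, so that a filter had been applied after calling. Scores and ratios of the authors were not compared between lists.

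Total counts per library ran from 642269 (Cebpb knockout CD11b low replicate 2) to 17834909 (5-week chimera wild-type replicate 2), and the floor of 3 counts stood for 0.168 to 4.67 CPM. Such floors and all counting intervals cover counting error only. Depth and the number of libraries limit which folds can be found (simulated data below).

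Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr with a minimum count of 10, dispersions were estimated with estimateDisp, and group means were compared with robust quasi-likelihood F tests. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg). Standard errors are the log2 fold change divided by the root of F. Each of the 27 comparisons was fitted on the libraries of its own experiment and within 1 table. Differences between effects were tested as interaction contrasts within a table. The strata comparison averaged the knockout effect of facility 1 females, facility 2 females and males. Calls of 3 Cebpb deletions with separate libraries were intersected, and their overlap was set beside that of independent lists.

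Gene lists, 22 in all, were tested with limma 3.58.1 camera at a preset correlation of 0.01: C/EBP family, GM-CSF receptor and STAT5 targets, MHC class II and co-stimulation, alveolar macrophage identity, cell cycle, cholesterol efflux and LXR targets, cholesterol synthesis, fatty acid oxidation, inflammatory cytokines and chemokines, lipid uptake with storage and PPAR targets, lipid-associated macrophage genes, lysosome and surfactant breakdown, monocyte and tissue macrophage markers, stress and dissociation, type I interferon response, and markers of dendritic cells, of eosinophils, mast cells and basophils, of epithelium, of erythroid cells, of lymphocytes, of neutrophils, and of stroma and endothelium. Members without counts in 1 group entered the printed medians also at a bound of 3 counts. This moved no median printed in the report.

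Named genes followed a rule. The targeted gene came first. The main comparisons then took the 8 largest rises and falls among called genes with at least 20 mean CPM in 1 group and no overlap of CPM between groups, and the others took 3. Predicted, mitochondrial and sex-linked genes were left out. Up to 4 members of each list that passed were added, with Pparg, Cebpa, Cebpd, Csf2ra, Csf2rb, Itgam, Siglecf, Fabp4, Fabp1, Cd36, Abca1, Abcg1 and Mki67. The report names a part of these, chosen for what the genes do. Counts of H2 genes, Oas genes, Ear1 and Ear2, Cyp4a12a and Cyp4a12b, hemoglobins, Csf2rb and Csf2rb2, Hspa1a and Hspa1b, Ccl and S100 genes are uncertain, since near-identical copies can share reads, and how such reads were counted is not given in the sources used here. The tables carry no strand, so overlapping antisense genes cannot be told apart.

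Peaks were merged with Python 3.11.15 and numpy 2.4.6 into regions (overlap of at least 1 bp) and each region was described by the libraries with a peak on it. Merging was checked against bedtools 2.31.1, and all 129652 ATAC regions were the same. Shares of regions were compared with Fisher's exact test (scipy 1.17.1, two-sided), with a logistic model for region width, or for mean expression and gene length. Genes were linked to a C/EBPβ region within 10 kb of the gene. The annotation used here gives no strand, so the distance ran to either gene end and not to a start site, a change from the plan. A search for C/EBP motifs needs a genome sequence and was not run. Figures were drawn with matplotlib 3.10.9.

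Whether replicate numbers pair the samples was checked from the correlation of deviations from the group means. Only Lip CD11b high and low cells passed (4 pairs, r 0.14 to 0.32, each library closest to its own number), which comes from the data and not from the labels. With the number as a block their count was 2085 against 1742. No 2 replicates were copies of each other (lowest chi-square per degree of freedom 1.83).

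Tests on simulated data used 200 changed genes, and rates hold there only. For CD11b low cells edgeR found 5.97%, 65.7% and 100% of genes changed 1.5, 2 and 4 times among 7497 genes, with 3.39% of calls false. For CD11cCre it found 46.3%, 95.5% and 100% among 9882 (5.29% false), for LyzMCre 2.99%, 19.4% and 89.4% among 8431 (14.9% false), and for the 5-week chimera 23.9%, 89.6% and 100% among 10858 (3.4% false). Camera found the 1 changed list in each, in LyzMCre only at the preset correlation, and no other. False calls of correlated lists were not tested.

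Groups, comparisons, tests, gene lists, the named-gene rule and these alternatives were fixed before the data were examined: DESeq2 1.42.0 size factors, its Wald test, no count filter, all samples of the count table in 1 fit, each replicate left out, the replicate number as a block, an absolute log2 fold change of at least 1, an estimated camera correlation, a −log10 q of at least 5, an overlap of 50%, lists of equal length and a distance of 50 kb. Chosen after seeing the data were libraries thinned to the smallest, the 10-week chimera without the libraries numbered 1, crossed replicate numbers in groups of 2, and a −log10 q of at least 10.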

Results

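Gene expression was measured by 3′ polyA RNA sequencing in 99 libraries of sorted mouse alveolar macrophages, the macrophages of the lung air spaces, and of related fetal lung cells. The labels place them in mutant groups and their controls, and the series states as its purpose the comparison of Cebpb mutant macrophages with their controls. Adult alveolar macrophages from lavage came from wild-type mice (n = 4) and mice without Cebpb, sorted into CD11b low (n = 4) and CD11b high (n = 4) cells. A second set of adult macrophages came from females of facility 1 (2 wild-type, 3 heterozygous and 2 knockout libraries), females of facility 2 (3 wild-type, 2 knockout) and males (2 wild-type, 2 knockout). Deletion with LyzMCre (2 control, 2 knockout) or with CD11cCre (3 control, 4 knockout) was measured in adult macrophages as well. Mice with the label Lip gave 4 CD11b low and 4 CD11b high libraries beside 3 controls. Premature alveolar macrophages of embryonic day 18 (E18) came from Cebpb (3 wild-type, 4 knockout) and Csf2rb (4 wild-type, 3 knockout) groups, and Ly6Chi fetal monocytes from E18 lungs (3 wild-type, 4 knockout). A further set, here called the chromatin-matched set, held adult Cebpb (3 wild-type, 3 knockout) and Lip (4 control, 4 Lip) libraries made beside chromatin libraries. Mixed bone marrow chimeras gave wild-type CD45.1 and CD11cCre Cebpb knockout CD45.2 alveolar macrophages at 5 weeks (3 and 4) and 10 weeks (4 and 3) after transfer.

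Total counts per library ran from 642269 to 17834909, and 9387 to 13579 genes had at least 1 count. Levels are CPM (counts scaled to library size with TMM factors), given as mean ± SD. Intervals and floors, where given, cover counting error only. Fold changes are on the log2 scale with standard errors (SE), mutant over control, from an edgeR quasi-likelihood fit, and adjusted p values follow Benjamini-Hochberg over all genes of a comparison. The labels name each library by group and replicate number, not by animal, so the p values measure the spread between samples. Positions are those of the mouse genome build GRCm38. Genes named as largest changes had no overlap of CPM between the groups compared. List calls come from the limma camera test at a preset correlation between genes, and a list printed without a value for an estimated correlation kept its call with that too.

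Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690432), which encodes the transcription factor C/EBPβ, was the targeted gene in most comparisons. Its level was 549 to 1460 CPM in the 4 adult wild-type libraries, 31.8 to 57.2 CPM in the 4 CD11b low knockout libraries and 24.7 to 86.9 CPM in the 4 CD11b high ones. Every other knockout library was below every library of its own controls: 40.6 to 48.7 against 1340 to 1810 CPM in females of facility 1, 56.3 to 157 against 1380 to 1580 CPM in females of facility 2, and 61.7 to 70.2 against 1880 to 1900 CPM in males. LyzMCre knockouts held 25.5 to 58.2 against 287 to 309 CPM, and CD11cCre knockouts 25.1 to 81.2 against 586 to 683 CPM. In E18 premature macrophages the ranges were 79.5 to 147 against 1710 to 2780 CPM, and in Ly6Chi monocytes 55.2 to 99.7 against 2080 to 3210 CPM. The chimeras held 18.1 to 36.8 against 915 to 941 CPM at 5 weeks and 24.6 to 113 against 1410 to 1730 CPM at 10 weeks. Knockouts of the chromatin-matched set held 9.61 to 31.6 against 422 to 529 CPM. Lip mutants kept Cebpb transcripts: 830 to 1000 CPM in CD11b low and 665 to 797 CPM in CD11b high cells against 502 to 685 CPM in their controls. Gene counts do not say whether the remaining knockout counts come from undeleted cells or from transcript outside the deleted part.

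**Figure D1:**
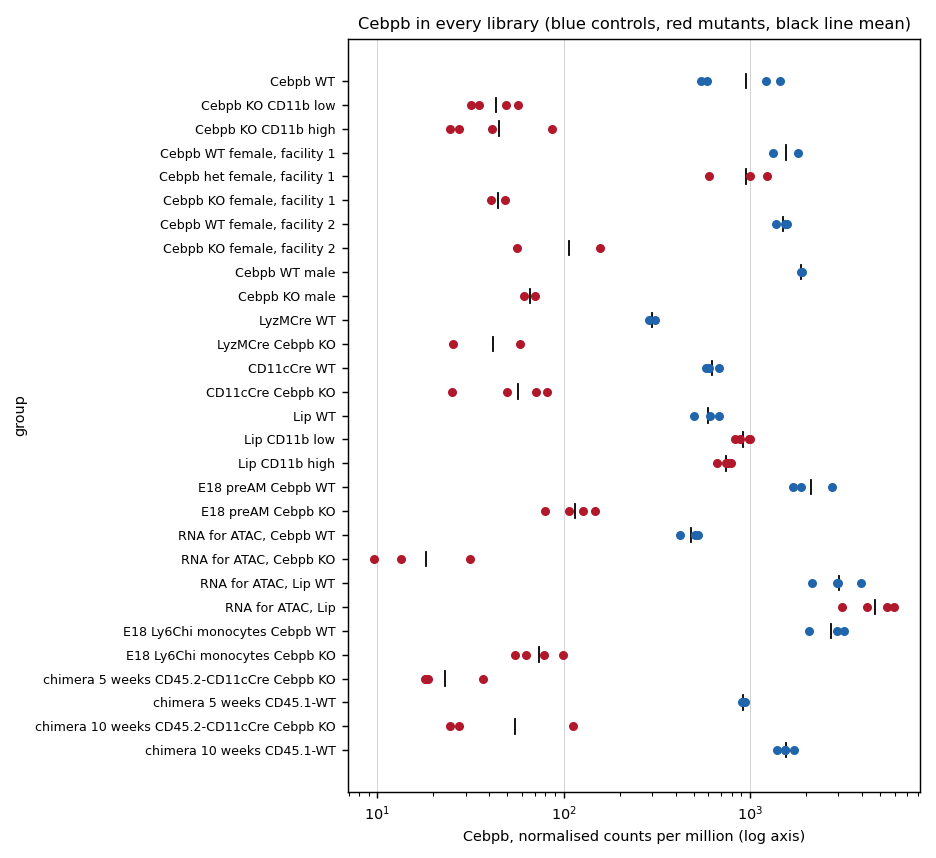
Normalised Cebpb CPM (log axis) in each RNA library by group, controls in blue, mutants in red, with the group mean as a black line. The CD11b low knockout libraries lie at 31.8 to 57.2 CPM and their 4 controls at 549 to 1460 CPM. Lip CD11b low libraries lie at 830 to 1000 CPM and their controls at 502 to 685 CPM.

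The comparison of Cebpb knockout CD11b low with wild-type adult macrophages (4 against 4) asks what the loss of C/EBPβ changes in the cells that keep the low CD11b surface level of alveolar macrophages. The complement gene C1qa was 2740 ± 1300 CPM against 25.4 ± 7.04 CPM (log2 fold change 6.72, SE 0.36, adjusted p 3.49e-10), and Cd74, the invariant chain of MHC class II, 5000 ± 2340 against 249 ± 69.4 CPM (4.33, SE 0.39, 3.38e-07). Apoe, a lipid carrier, rose from 1330 ± 96.9 to 23200 ± 1750 CPM. Markers of alveolar macrophages fell: Krt79 to 15.6 ± 17.7 from 785 ± 130 CPM (−5.94, SE 0.66, 1.29e-05) and the scavenger receptor Marco to 25.7 ± 41 from 898 ± 236 CPM (−5.44, SE 0.88, 8.89e-04). Pparg (ENSMUSG00000000440, chromosome 6, 115360879 to 115490404), a nuclear receptor of lipid metabolism, fell to 73.9 ± 14.8 from 246 ± 89.1 CPM (−1.71, SE 0.25, 6.60e-05), where gene counts cannot tell its isoforms apart. In all, 1286 of 8502 genes passed, 705 higher and 581 lower.

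Of the 26 genes of the alveolar macrophage identity list, 14 fell and 3 rose over all genes (15 and 3 adjusted over the list alone), with a median log2 fold change of −1.01 (camera adjusted p 1.69e-09). The risers were Flt1 (2.88), Ctsk (1.64) and Bhlhe40 (0.91). Siglecf fell to 67.6 ± 26 from 355 ± 56.3 CPM and Fabp1 to 71.2 ± 22.6 from 534 ± 72.2 CPM. Among 20 lipid uptake, storage and PPAR target genes 6 fell and 1, Pdk4 (2.18), rose (7 and 1 adjusted over the list alone; adjusted p 1.32e-04, or adjusted p = 0.0708 with an estimated correlation). Cd36 (−0.44, SE 0.25) and Fabp4 (−0.56, SE 0.31) did not pass, and Fabp4 moved to −0.26 without wild-type replicate 2 and to −0.35 without knockout replicate 3. Cholesterol synthesis genes fell in 11 of 16 cases and rose in 0 (11 and 0 adjusted over the list alone; median −1.27, adjusted p 2.70e-08), among them Sqle (−2.57, SE 0.40). Of 17 cholesterol efflux and LXR target genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.36, adjusted p 2.70e-04, or adjusted p = 0.0708 with an estimated correlation). Abca1 rose to 104 ± 24.4 from 19.7 ± 6.65 CPM, and Abcg1 did not pass (−0.61, SE 0.25). Fatty acid oxidation genes fell in 4 of 22 cases and rose in 0 (4 and 0 adjusted over the list alone; adjusted p 0.026, or adjusted p = 0.326 with an estimated correlation).

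All 9 measured genes of the MHC class II and co-stimulation list rose (9 adjusted over the list alone; median 4.33, adjusted p 8.42e-16), with H2-Eb1 at 2500 ± 1290 against 74.4 ± 15.3 CPM. The 15 monocyte and tissue macrophage markers gave 9 higher and 2 lower genes (10 and 3 adjusted over the list alone; median 1.87, adjusted p 6.08e-12), the lower ones being Treml4 and Nr4a1 (−1.78, SE 0.42). Lipid-associated macrophage genes rose in 7 of 14 cases and fell in 0 (7 and 0 adjusted over the list alone; adjusted p 3.48e-07, or adjusted p = 0.0708 with an estimated correlation), with Trem2 at 986 ± 299 against 145 ± 30.7 CPM. Type I interferon response genes rose in 9 of 22 cases and fell in 0 (9 and 0 adjusted over the list alone; adjusted p 0.00246, or adjusted p = 0.573 with an estimated correlation), Oasl2 by 3.04 (SE 0.60). Cell cycle genes fell in 12 of 24 cases and rose in 0 (14 and 0 adjusted over the list alone; median −1.17, adjusted p 5.01e-06, or adjusted p = 0.221 with an estimated correlation), among them Top2a (−2.03, SE 0.39).

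Other lists did not pass in this comparison. Lysosome and surfactant breakdown genes gave 5 higher and 2 lower of 24 (6 and 4 adjusted over the list alone; adjusted p 0.289), GM-CSF receptor and STAT5 target genes 5 and 3 of 14 (5 and 3 adjusted over the list alone; 0.348) and stress and dissociation genes 1 and 1 of 12 (1 and 1 adjusted over the list alone; 0.711). Inflammatory cytokines and chemokines gave 5 higher and 5 lower of 17 (5 and 5 adjusted over the list alone; 0.951), with a median of −0.2, a mean of 0.32 and a test direction of lower. The C/EBP family gave 1 higher, Ddit3, and 1 lower, Cebpb, of 5 (1 and 1 adjusted over the list alone; 0.801), with a median of 0.41, a mean of −0.34 and a test direction of lower. Markers of other cells gave, for neutrophils, 1 higher of 3 (1 adjusted over the list alone; 0.188; median −0.07, mean 1.12, test direction higher), for epithelium 0 of 2 (0 adjusted over the list alone; 0.873) and for erythroid cells 0 of 4 (2 higher adjusted over the list alone; 0.0539). No gene of the lymphocyte, dendritic cell, stroma and endothelium, or eosinophil, mast cell and basophil lists passed the count filter.

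Cebpb knockout CD11b high cells (n = 4) gave 2044 genes against the wild-type group (1039 higher, 1005 lower). Pparg was 38.1 ± 9.52 CPM there (−2.70, SE 0.26, adjusted p 2.74e-07), Siglecf 17.9 ± 7.71 CPM and Fabp1 18.8 ± 14 CPM. Alveolar macrophage identity genes fell in 19 cases and rose in 3 of 26 (20 and 3 adjusted over the list alone; median −2.94, adjusted p 3.64e-21). Against the CD11b low knockout cells directly (4 against 4), 101 genes were higher and 222 lower. The receptor Kit rose to 42.2 ± 17.3 from 4.16 ± 3.06 CPM (3.53, SE 0.47, 1.61e-04), and the prostaglandin dehydrogenase Hpgd fell to 7.67 ± 0.592 from 136 ± 84.5 CPM (−4.16, SE 0.41, 1.66e-05). In this direct comparison 14 identity genes fell and 0 rose (15 and 0 adjusted over the list alone; median −1.05, adjusted p 2.17e-25). Of 20 lipid uptake, storage and PPAR target genes 9 fell and 0 rose (10 and 2 adjusted over the list alone). Its 323 genes became 152 without CD11b low replicate 1, 210 without CD11b low replicate 3, 193 without CD11b high replicate 2 and 208 without CD11b high replicate 4.

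Knockout and wild-type macrophages of both facilities and sexes, compared within each stratum and averaged (6 knockout, 7 wild-type libraries), ask whether the change recurs outside the first set of mice. Krt79 fell in each stratum, to 12.4 ± 8.69 from 1240 ± 137 CPM in females of facility 1, to 1.75 ± 0.658 from 810 ± 50 CPM in facility 2 and to 11.4 ± 1.49 from 815 ± 53.1 CPM in males. The chitinase-like Chil3 (−5.70, SE 0.24, adjusted p 9.47e-12), the lipid droplet gene Cidec (−4.56, SE 0.31) and Siglecf (−3.15, SE 0.31) fell as well. The elastase Mmp12 rose by 6.32 (SE 0.23, 1.14e-12) and Cd74 by 3.92 (SE 0.44). Pparg fell to 64.1 ± 19.9 from 236 ± 4.8 CPM in facility 1, to 29.5 ± 12.1 from 382 ± 32.8 CPM in facility 2 and to 93.7 ± 30.8 from 238 ± 92.6 CPM in males (mean −2.28, SE 0.18, 2.13e-08). Genes passed in 5018 cases of 11040, 2582 higher and 2436 lower.

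Over these strata 14 of 20 monocyte and tissue macrophage markers rose and 1 fell (15 and 1 adjusted over the list alone; median 3.69, adjusted p 4.61e-15). Of 26 identity genes 18 fell and 5 rose (18 and 6 adjusted over the list alone; median −1.95). Cell cycle genes fell in 38 of 39 cases and rose in 0 (38 and 0 adjusted over the list alone; median −1.66, adjusted p 5.73e-15, or adjusted p = 0.0615 with an estimated correlation), among them Mcm3 (−1.25, SE 0.12). Interferon response genes rose in 21 of 26 cases and fell in 1, Cxcl9 (21 and 1 adjusted over the list alone; adjusted p 9.33e-08, or adjusted p = 0.26 with an estimated correlation). MHC class II genes rose in 9 of 12 cases (9 adjusted over the list alone; adjusted p 3.31e-04, or adjusted p = 0.158 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 19 cases and rose in 0 (15 and 0 adjusted over the list alone; adjusted p 2.21e-04, or adjusted p = 0.43 with an estimated correlation), among them Fdft1 (−1.71, SE 0.26). Of the dendritic cell markers 1, Clec10a, rose of 2 (1 and 1 adjusted over the list alone; adjusted p 0.578), of the neutrophil markers 2, Cxcr2 and S100a8, of 3 (2 adjusted over the list alone; 0.572) and of stroma and endothelium 1 of 3 (1 adjusted over the list alone; 0.396). No lymphocyte, epithelial or erythroid marker was called. Of these calls, Cxcr2 was lost without knockout replicate 2 of facility 2, and S100a8 without each of 7 of the 13 libraries.

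The effect of the knockout differed between the facilities for 840 genes by an interaction test (380 with a higher and 460 with a lower fold change in facility 2). Of the interferon response genes 11 passed upward and 0 downward (21 and 0 adjusted over the list alone; adjusted p 1.85e-22, or adjusted p = 0.149 with an estimated correlation). Irf7 had a difference of 5.11 (SE 0.71, adjusted p 0.00174). Cidec (−4.97, SE 0.76) and Pparg (−1.76, SE 0.43, 0.0188) fell further in facility 2, where the Pparg call was lost without wild-type replicate 2 (−1.81) or knockout replicate 1 (−1.43) of facility 1. Males differed from the mean of the females for 1169 genes, with less of a rise of C1qc (−6.19, SE 0.52) and less of a fall of Cidec (4.20, SE 0.59). The labels of males give no facility, so sex is not separated from it. Of the identity genes 15 differed upward and 0 downward (17 and 0 adjusted over the list alone; adjusted p 3.11e-15). The facility count was 494 and 534 without wild-type replicates 1 and 2 of facility 2 (full range below). Damaged cells could add to the facility difference, as facility 2 knockouts held more mitochondrial counts (below). This was not tested. The count of males against females was 777 without knockout replicate 2 of facility 1, 1931 without knockout replicate 1 of facility 2, and 395, 334, 343 and 537 without male wild-type replicates 1 and 2 and male knockout replicates 1 and 2.

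Within the strata 2565 genes passed in facility 1, 5253 in facility 2 and 1201 in males. The counts of facility 1 and males fell with each replicate left out (ranges below). Mitochondrial counts took 0.89 to 1.22% of facility 2 knockout libraries and 0.04 to 0.06% of their controls. In facility 1 these were 0.22 to 0.48% and 0.06 to 0.14%.

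Heterozygous females of facility 1 (3 against 2 wild-type) ask whether 1 Cebpb copy suffices. Cebpb was 951 ± 318 CPM in heterozygous and 1570 ± 331 CPM in wild-type cells (−0.72, SE 0.32, adjusted p 0.392), and Pparg 260 ± 46.7 and 236 ± 4.8 CPM. Car4, a carbonic anhydrase on alveolar macrophages, fell to 83.5 ± 49.5 from 652 ± 330 CPM (−2.97, SE 0.46, 0.0107). Of the monocyte and tissue macrophage markers 4 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p 4.08e-12), at low level: C1qa was 16.3 ± 1.14 CPM against 0.403 ± 0.232 CPM. The 70 genes called were 29 without wild-type replicate 1, 23 without wild-type replicate 2 and 38 without heterozygous replicate 2. Car4 lost its call without wild-type replicate 2 (−2.35). Knockout against heterozygous cells gave 2336 genes, and 1099 without knockout replicate 2.

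LyzMCre deletion (2 against 2) asks what Cebpb loss through a Cre expressed in myeloid cells changes. Marco fell to 21.5 ± 12.9 from 1600 ± 58.3 CPM (−6.06, SE 0.45, adjusted p 1.95e-04), Car4 to 22.8 ± 2.82 from 1140 ± 77.5 CPM and Krt79 to 18.4 ± 1.42 from 703 ± 61.9 CPM. Apoe rose to 18200 ± 10600 from 396 ± 182 CPM and Abca1 to 71.4 ± 13 from 7.38 ± 1.9 CPM. Pparg was 79 ± 29.4 against 181 ± 46.2 CPM and did not pass (−1.16, SE 0.32, 0.0943), but passed without knockout replicate 1 (−0.87) or 2 (−1.65), without a count filter and with all samples of the count table. MHC class II genes rose in 7 of 10 cases and fell in 0 (9 and 0 adjusted over the list alone; median 2.23, adjusted p 2.26e-17, or adjusted p = 0.155 with an estimated correlation). The 405 genes called (256 higher, 149 lower) were 214 and 245 without wild-type replicates 1 and 2, and 1877 and 2747 without knockout replicates 1 and 2.

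CD11cCre deletion (4 knockout, 3 control libraries) removes Cebpb from cells that express Itgax, the gene of CD11c, which include alveolar macrophages. The chemokine Ccl17 rose to 957 ± 354 from 7.67 ± 0.385 CPM (6.96, SE 0.31, adjusted p 9.33e-08). Mmp12 rose to 358 ± 96.2 from 3.91 ± 2.81 CPM, H2-Eb1 to 1360 ± 472 from 42.2 ± 16.4 CPM and Cd74 to 6830 ± 1740 from 250 ± 36.3 CPM. The lower genes included Car4, at 17.2 ± 5.89 against 507 ± 73.1 CPM (−4.90, SE 0.23, 9.33e-08), Fpr2, at 16.3 ± 7.44 against 330 ± 39 CPM, and the short-chain fatty acid receptor Ffar2, at 8.15 ± 5.21 against 89.5 ± 9.02 CPM. Pparg was 170 ± 17.2 against 241 ± 9.34 CPM (−0.51, SE 0.11, 0.00821). Siglecf was not called (−0.41, SE 0.15, 0.0942). Fabp4, a fatty acid carrier, rose to 550 ± 139 from 205 ± 20.9 CPM. Genes passed in 1677 cases of 9992 (1030 higher, 647 lower).

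Under CD11cCre MHC class II genes rose in 10 of 11 cases and fell in 0 (10 and 0 adjusted over the list alone; median 2.84, adjusted p 1.36e-29). Lipid-associated macrophage genes rose in 10 of 14 (11 and 0 adjusted over the list alone; median 0.91, adjusted p 6.44e-11), with Trem2 at 3.16 (SE 0.18). Identity genes split, 11 falling and 7 rising of 26 (12 and 7 adjusted over the list alone; adjusted p 0.00407, or adjusted p = 0.172 with an estimated correlation). The risers were Fabp4, Flt1, Bhlhe40, Slc7a2, Plet1, Itgax and Ctsk. Cell cycle genes fell in 17 of 39 cases and rose in 0 (26 and 0 adjusted over the list alone; adjusted p 5.97e-08, or adjusted p = 0.154 with an estimated correlation). All 4 measured neutrophil markers rose (4 adjusted over the list alone; median 1.68, adjusted p 5.97e-08), Cxcr2 to 218 ± 38.2 from 11 ± 3.75 CPM and S100a8 to 81.1 ± 24.9 from 22.9 ± 0.925 CPM. Clec9a, the 1 dendritic cell marker measured, fell (−2.75). The call count was 1095 without control replicate 1 and 2688 without knockout replicate 4. In a fit with all samples of the count table Pparg (−0.51) and Fabp4 (1.41) lost their calls.

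**Figure D2:**
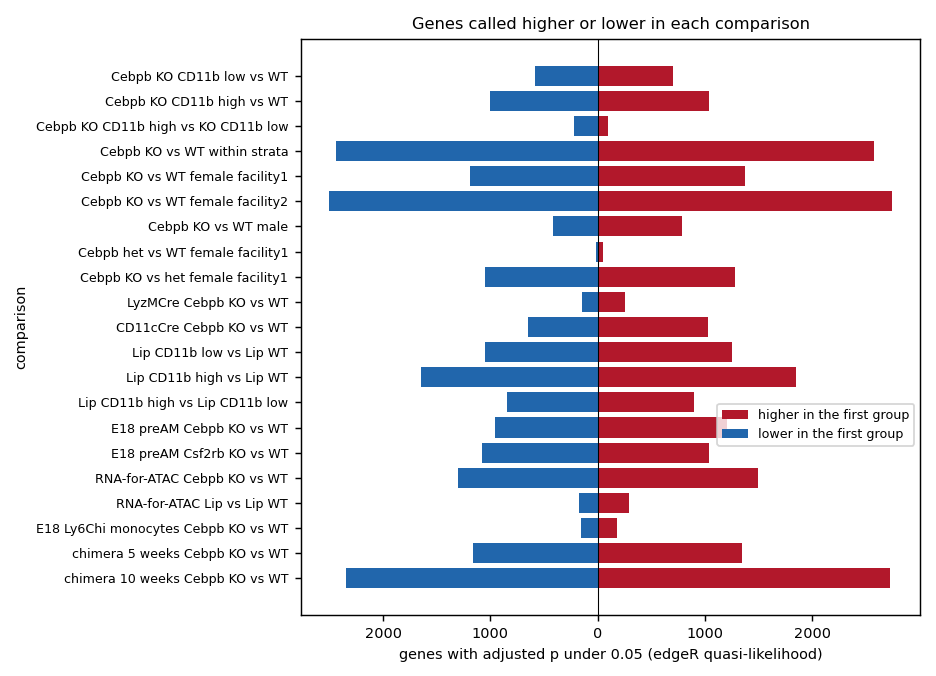
Number of genes higher and lower at an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg) in each comparison of groups, as bars. The count ran from 70 in heterozygous females to 5253 in knockout females of facility 2.

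The 3 Cebpb deletions that share no library (CD11b low, strata and CD11cCre) had 409 genes higher and 248 lower in all, of 8404 genes tested in each, where independent lists would give 15.9 and 8.23. Across genes the log2 fold changes correlated with Pearson coefficients of 0.84 between CD11b low and strata, 0.73 between CD11b low and CD11cCre, and 0.77 between strata and CD11cCre (Spearman 0.6, 0.44 and 0.57), where genes are not independent replicates. Genes lower in all 3 included Krt79 (chromosome 15, 101929332 to 101940324), Car4 (chromosome 11, 84957754 to 84966054), Marco (chromosome 1, 120474538 to 120505024), Fpr2 and Ffar2. Genes higher in all 3 included H2-Eb1 (5.08, 5.68 and 5.01 in the same order), Mmp12 (4.24, 6.32 and 6.51), the growth factor Csf1 (3.68, 5.31 and 5.72) and Cd74.

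**Figure D3:**
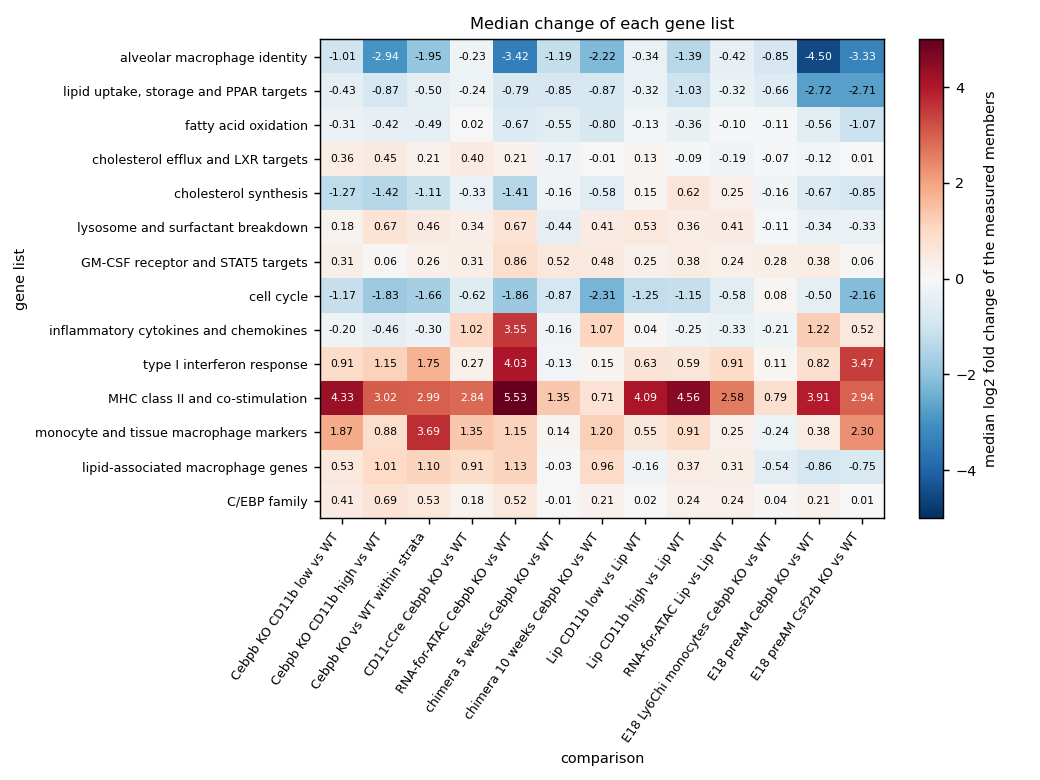
Median log2 fold change of the measured genes of 14 lists (rows) in 13 comparisons (columns), as colour from lower (blue) to higher (red) in mutants. The MHC class II list has a median of 4.33 in CD11b low knockout cells and 2.84 under CD11cCre, and the alveolar macrophage identity list −1.01 and −0.23.

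Lip CD11b low macrophages (n = 4) against their controls (n = 3) ask how this mutant, which keeps Cebpb transcripts, compares with the knockout. Mfge8 rose to 1780 ± 140 from 11.6 ± 3.9 CPM (7.34, SE 0.16, adjusted p 2.88e-36), and the MHC class II activator Ciita to 110 ± 23.9 from 6.22 ± 1 CPM. The thiolase Acaa1b fell to 6.94 ± 3.37 from 516 ± 116 CPM (−6.21, SE 0.20, 5.92e-20), Lepr to 1.36 ± 0.833 from 68.6 ± 21.8 CPM and Marco to 38.3 ± 19.2 from 843 ± 231 CPM. Pparg fell to 115 ± 10.1 from 260 ± 38.1 CPM (−1.19, SE 0.11, 3.35e-12). Cebpb rose by 0.63 (SE 0.10, 4.65e-06), a call lost in a fit with all samples of the count table (0.65). Genes passed in 2305 cases of 8918 (1251 higher, 1054 lower).

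All 9 measured MHC class II genes rose in Lip CD11b low cells (9 adjusted over the list alone; median 4.09, adjusted p 3.15e-58), and lysosome and surfactant breakdown genes rose in 14 of 24 cases and fell in 0 (15 and 0 adjusted over the list alone; median 0.53, adjusted p 4.62e-10), Npc2 among them. Identity genes fell in 12 and rose in 6 of 26 cases (12 and 6 adjusted over the list alone; median −0.34, adjusted p 1.16e-15). Lipid uptake, storage and PPAR target genes fell in 10 and rose in 4 of 20 (11 and 5 adjusted over the list alone; adjusted p 1.54e-06). Fabp4 (−2.23, SE 0.18) was among the lower ones, and Pdk4, Msr1, Mgll and Hilpda were the higher ones. Lipid-associated macrophage genes gave 6 higher and 4 lower (6 and 5 adjusted over the list alone), with a median of −0.16, a mean of 0.54 and a test direction of higher (adjusted p 0.016, or adjusted p = 0.172 with an estimated correlation). Of 3 neutrophil markers 2, Csf3r and Cxcr2, fell and 0 rose (2 and 0 adjusted over the list alone; median −2.86, adjusted p 1.56e-04), Csf3r to 7.73 ± 3.5 from 53.4 ± 7.72 CPM. Of 4 erythroid markers 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p 0.00372, or adjusted p = 0.237 with an estimated correlation).

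Lip CD11b high cells (n = 4) gave 3505 genes against the controls, with Pparg at 50.5 ± 2.47 CPM (−2.37, SE 0.13, adjusted p 5.88e-21) and Marco at 6.37 ± 2.65 CPM. Against Lip CD11b low cells (4 against 4; 897 higher, 845 lower) the lectin Mgl2 rose to 314 ± 69 from 6.01 ± 5.16 CPM (5.52, SE 0.35) and fibronectin, Fn1, to 828 ± 201 from 126 ± 23.2 CPM. Identity genes fell in 19 cases and rose in 1 between them (20 and 2 adjusted over the list alone; median −1.02). Cholesterol synthesis genes rose in 10 cases and fell in 0 (14 and 0 adjusted over the list alone), Sqle by 1.41 (SE 0.18), with adjusted p = 0.089 with an estimated correlation. In the chromatin-matched set Lip mutants not split by CD11b (4 against 4) gave 469 genes. Genes of MHC class II were higher in 9 of 10 cases and lower in 0 (9 and 0 adjusted over the list alone; median 2.58, adjusted p 3.95e-37), Mgl2 was 40.3 ± 22.1 against 1.17 ± 0.963 CPM and Lepr 1.44 ± 1.02 against 55.9 ± 21.1 CPM. Pparg, at 108 ± 31.4 against 187 ± 49.1 CPM, did not pass (−0.78, SE 0.25, 0.104), except without Lip replicate 4 (−1.01).

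The difference between the Lip and the Cebpb knockout effect in CD11b low cells passed an interaction test for 446 genes (276 upward, 170 downward in Lip). Of 18 cholesterol synthesis genes 10 passed upward and 0 downward (15 and 0 adjusted over the list alone; adjusted p 1.17e-11), with Sqle at 2.39 (SE 0.46) and Msmo1 at 1.55 (SE 0.29). Cholesterol efflux genes differed downward in 5 cases and upward in 1 (6 and 1 adjusted over the list alone). Monocyte and tissue macrophage markers differed downward in 4 and upward in 2 (7 and 2 adjusted over the list alone). Apoe (−5.13, SE 0.68), Flt1 (−7.77, SE 0.58), Trem2 (−3.10, SE 0.28) and the neutrophil receptor Cxcr2 (−7.90, SE 0.68) had lower fold changes in Lip. Car4 (4.84, SE 0.67) and Il18 (2.45, SE 0.23) had higher ones. Pparg did not differ by this test (0.50, SE 0.29, adjusted p 0.395), with 0.23 without wild-type replicate 1 of the Cebpb set.

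Adult Cebpb knockout macrophages of the chromatin-matched set (3 against 3) describe RNA of cells prepared beside chromatin libraries. C1qa rose to 3840 ± 1480 from 10.7 ± 4.6 CPM (8.48, SE 0.47, adjusted p 8.38e-06), H2-Eb1 to 4000 ± 1470 from 35.1 ± 10.5 CPM and the interferon-induced Oasl2 to 216 ± 125 from 6.56 ± 1.1 CPM. Siglecf fell to 19.3 ± 8.48 from 381 ± 17.3 CPM, Fabp1 to 8.89 ± 5.73 from 514 ± 116 CPM and Pparg to 19.2 ± 5.77 from 190 ± 47 CPM (−3.31, SE 0.28, 3.27e-05). Interferon response genes rose in 25 of 26 cases and fell in 0 (25 and 0 adjusted over the list alone; median 4.03, adjusted p 3.09e-14), with adjusted p = 0.269 with an estimated correlation. Cell cycle genes fell in 33 of 38 cases and rose in 0 (34 and 0 adjusted over the list alone), with adjusted p = 0.056 with an estimated correlation. All 5 neutrophil markers rose (5 adjusted over the list alone), S100a9 to 212 ± 107 from 1.67 ± 0.812 CPM, with adjusted p = 0.112 with an estimated correlation. Of 6 erythroid markers 5 rose (6 adjusted over the list alone), with adjusted p = 0.233 with an estimated correlation. Genes passed in 2795 of 10262 cases.

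E18 premature alveolar macrophages (4 knockout, 3 wild-type) ask whether Cebpb acts before birth. Pparg fell to 7.53 ± 1.68 from 171 ± 11.2 CPM (−4.50, SE 0.23, adjusted p 2.85e-08). Car4 fell to 0.995 ± 0.673 from 81 ± 3.47 CPM, galanin, Gal, to 3.05 ± 3.35 from 597 ± 81.6 CPM (−7.50, SE 0.72, 9.96e-05), Fn1 to 50.6 ± 24.1 from 1810 ± 317 CPM and Lpl to 99.8 ± 26.2 from 1250 ± 264 CPM. The MHC class II gene H2-Aa rose to 17000 ± 4140 from 621 ± 345 CPM (4.77, SE 0.47, 6.82e-06), Cd209a to 461 ± 162 from 7.36 ± 2.4 CPM and Mgl2 to 195 ± 110 from 2.05 ± 1.7 CPM. Siglecf rose to 12.5 ± 6.18 from 2.36 ± 0.79 CPM (2.41, SE 0.53, 0.00428). Of 10047 genes 2164 passed (1205 higher, 959 lower).

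Of 18 measured lipid uptake, storage and PPAR target genes 14 fell and 1 rose before birth (15 and 1 adjusted over the list alone; median −2.72, adjusted p 1.70e-26), with Plin2 at 87.8 ± 14.2 against 482 ± 81.5 CPM and Dgat2 at −2.96 (SE 0.22), while Lipe rose (1.44). Identity genes fell in 17 and rose in 3 of 23 cases, Siglecf, Bhlhe40 and Itgax (17 and 3 adjusted over the list alone; median −4.5, adjusted p 3.53e-21). Lipid-associated macrophage genes fell in 7 and rose in 0 of 14 (8 and 0 adjusted over the list alone; adjusted p 2.70e-07), with Spp1 at −2.26 (SE 0.26). MHC class II genes rose in 11 of 12 cases and fell in 0 (11 and 0 adjusted over the list alone; median 3.91, adjusted p 5.52e-20). All 4 measured dendritic cell markers rose (4 adjusted over the list alone; median 3.5, adjusted p 6.68e-11), Flt3 by 2.82 and Zbtb46 by 3.29. Epithelial markers rose in 3 of 5 cases (4 adjusted over the list alone; adjusted p 0.0102, or adjusted p = 0.143 with an estimated correlation), and the 1 measured gene of the eosinophil, mast cell and basophil list was not called.

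The knockout effect differed between E18 and adult CD11b low macrophages for 1084 genes (437 upward, 647 downward before birth). Dendritic cells in the sort may add to the E18 effect (not tested). Pparg fell further before birth (−2.78, SE 0.35, adjusted p 3.28e-06), as did Fabp4 (−6.71, SE 0.97), Lpl (−3.81, SE 0.40) and Fn1 (−7.98, SE 0.42), while Siglecf differed upward (4.79, SE 0.49). Lipid uptake, storage and PPAR target genes differed downward in 11 cases and upward in 0 of 20 (14 and 1 adjusted over the list alone; adjusted p 2.55e-17). Lipid-associated macrophage genes differed downward in 12 of 14 (12 adjusted over the list alone; adjusted p 4.04e-22), with Trem2 at −3.71 (SE 0.33). MHC class II genes did not differ as a list (1 upward and 1 downward, 2 and 1 adjusted over the list alone; adjusted p 0.204).

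**Figure D4:**
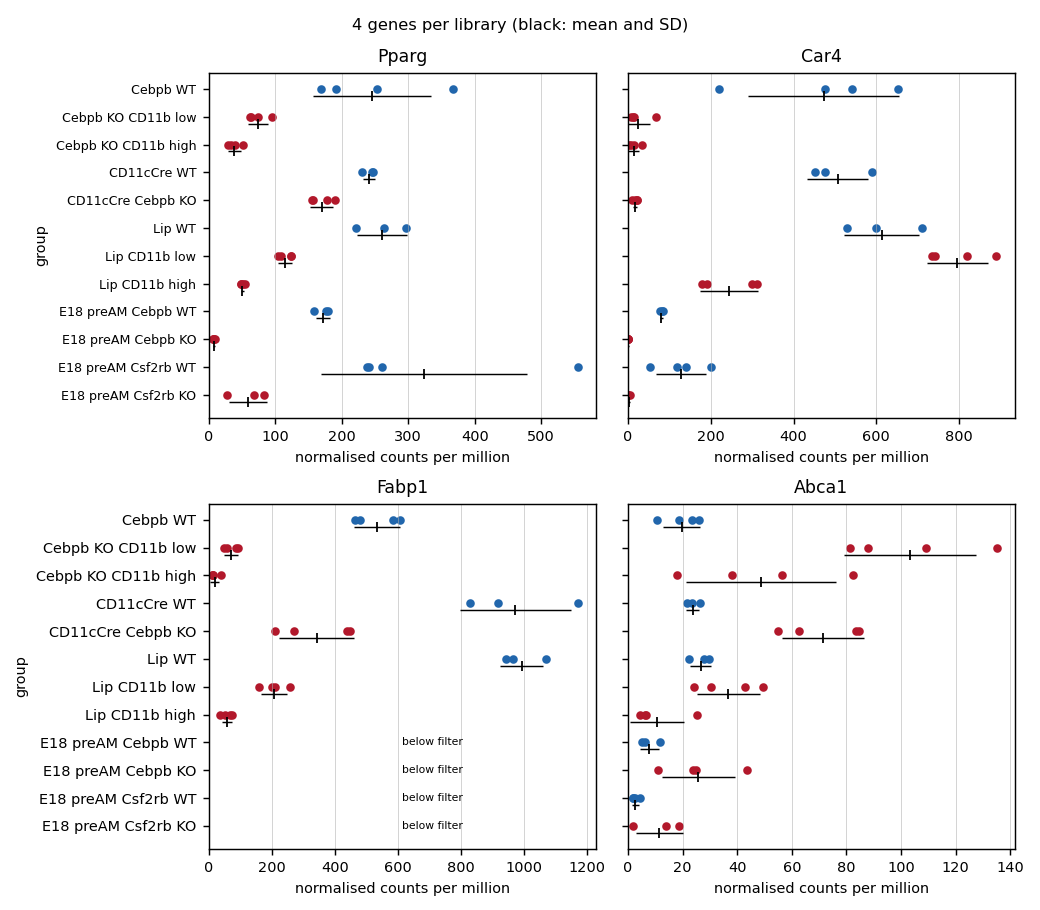
CPM per library (points) of Pparg, Car4, Fabp1 and Abca1 with group mean and SD (lines), for controls and mutants of each set of samples. Pparg is 73.9 ± 14.8 against 246 ± 89.1 CPM in adult CD11b low cells and 7.53 ± 1.68 against 171 ± 11.2 CPM at E18, where Fabp1 is below the count filter.

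Loss of Csf2rb, the shared chain of the GM-CSF receptor, in E18 premature macrophages (3 knockout, 4 wild-type libraries) asks what this signal does in the same cells. Csf2rb (ENSMUSG00000071713, chromosome 15, 78325800 to 78351001) was 293 to 360 CPM in the knockout libraries and 763 to 1170 CPM in the wild-type ones (−1.62, SE 0.20, adjusted p 4.95e-04). Gene counts do not say whether the counts left lie outside the deleted part. Plet1 fell to 2.99 ± 3.05 from 713 ± 6.97 CPM (−8.07, SE 0.55, 1.50e-05), Fn1 to 104 ± 30.8 from 2210 ± 240 CPM, Lpl to 84.2 ± 69.9 from 1620 ± 737 CPM and Pparg to 59.3 ± 28.6 from 324 ± 154 CPM (−2.46, SE 0.45, 0.00434). Tmem176b rose to 1040 ± 233 from 7.19 ± 2.14 CPM (7.15, SE 0.31, 1.89e-06), C1qb to 4600 ± 1110 from 56.9 ± 8.66 CPM and the interferon regulator Irf7 to 1420 ± 491 from 66.8 ± 21.7 CPM. The 2118 genes called (1040 higher, 1078 lower) were 1411, 1392 and 1325 without wild-type replicates 1, 3 and 4. Knockout libraries held counts in 9387 to 9418 genes and wild-type ones in 11639 to 12557.

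All 24 measured interferon response genes rose in Csf2rb knockouts (24 adjusted over the list alone; median 3.47, adjusted p 7.42e-35), Isg15 to 877 ± 421 from 20 ± 6.63 CPM. Monocyte and tissue macrophage markers rose in 14 and fell in 1, Fn1, of 22 cases (14 and 1 adjusted over the list alone; median 2.3, adjusted p 5.02e-17). Of 10 MHC class II genes 6 rose and 0 fell (7 and 0 adjusted over the list alone). Of 3 dendritic cell markers 2, Flt3 and Cd209a, rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p 0.00236, or adjusted p = 0.0588 with an estimated correlation). Lipid uptake, storage and PPAR target genes fell in 13 and rose in 1, Lipe, of 18 (14 and 1 adjusted over the list alone; median −2.71, adjusted p 1.75e-10). Fatty acid oxidation genes fell in 10 of 22 (11 adjusted over the list alone; adjusted p 4.64e-05), with Ech1 at −2.62 (SE 0.41) and Cpt1a at −1.67 (SE 0.26). Cell cycle genes fell in 22 of 39 cases and rose in 0 (30 and 0 adjusted over the list alone; median −2.16), with adjusted p = 0.0544 with an estimated correlation. All 5 erythroid markers rose (5 adjusted over the list alone; adjusted p 2.37e-06), Hba-a1 to 2410 ± 590 from 484 ± 60.4 CPM, with adjusted p = 0.121 with an estimated correlation. Of 3 eosinophil, mast cell and basophil markers 1, Gata2, rose (2 adjusted over the list alone), with adjusted p = 0.131 with an estimated correlation.

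Between the Csf2rb and the Cebpb knockout effect at E18, 1157 genes differed (426 upward, 731 downward for Csf2rb). Pparg fell less with Csf2rb loss (1.99, SE 0.50, adjusted p 0.0153), Irf7 (4.08, SE 0.41) and Plac8 (6.22, SE 0.55) rose further, and the STAT5 target Cish differed downward (−4.26, SE 0.45). Interferon response genes differed upward in 20 of 25 cases and downward in 0 (24 and 0 adjusted over the list alone; adjusted p 3.75e-34). Cell cycle genes differed downward in 18 of 39 and upward in 0 (26 and 0 adjusted over the list alone; adjusted p 8.71e-17). Lipid uptake, storage and PPAR target genes differed in 2 cases each way. The count was 749 without Cebpb wild-type replicate 1 and 1871 without Csf2rb knockout replicate 2.

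Ly6Chi fetal monocytes (4 knockout, 3 wild-type libraries), a source population of alveolar macrophages, ask whether the change is present before these cells mature. The matrix proteoglycan Vcan fell to 1.49 ± 1.52 from 73.3 ± 13.2 CPM (−5.30, SE 0.40, adjusted p 7.36e-07), Chil3 to 12.9 ± 7.95 from 448 ± 81.2 CPM and Lpl to 20.1 ± 13.4 from 140 ± 14.9 CPM. H2-Eb1 rose to 489 ± 132 from 91.1 ± 13.8 CPM (2.43, SE 0.24). Pparg was 15.3 ± 5.2 against 36.7 ± 3.67 CPM (−1.23, SE 0.28, 0.0176), a call lost without wild-type replicate 1 (−1.16), 2 (−1.28) or 3 (−1.27), and with all samples of the count table (−1.23). The 334 genes called (183 higher, 151 lower) were 162, 114 and 166 without wild-type replicates 1, 2 and 3, 191 without knockout replicate 1 and 176 without knockout replicate 4.

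In these monocytes 5 of 11 MHC class II genes rose and 0 fell (7 and 0 adjusted over the list alone; median 0.79, adjusted p 9.21e-14). Of 15 lipid uptake, storage and PPAR target genes 5 fell and 0 rose (8 and 0 adjusted over the list alone; median −0.66, adjusted p 1.36e-06). Monocyte and tissue macrophage markers fell in 4 and rose in 1 of 22 cases (4 and 1 adjusted over the list alone; adjusted p 8.61e-05). Vcan, Fn1 (−1.40), Cd14 and Treml4 were the lower ones. Neutrophil markers gave 1 higher and 2 lower of 9 (1 and 2 adjusted over the list alone; adjusted p 0.512), Cxcr2 rising and S100a8 falling to 90.7 ± 9.19 from 810 ± 319 CPM, with a median of 1.27, a mean of 0.73 and a test direction of lower. Epithelial markers rose in 1, Cdh1, of 4 (1 adjusted over the list alone; adjusted p 0.00274, or adjusted p = 0.293 with an estimated correlation), eosinophil, mast cell and basophil markers in 1, Gata2, of 2 (2 adjusted over the list alone; adjusted p 0.00518, or adjusted p = 0.121 with an estimated correlation), and dendritic cell markers in 0 of 3 (1 adjusted over the list alone; adjusted p 0.0437, or adjusted p = 0.291 with an estimated correlation). The Gata2 call was lost without any 1 library other than knockout replicate 3. Knockout replicate 2 held 835 CPM of the epithelial Sftpc and knockout replicate 3 18700 CPM of Hbb-bs.

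The chimeras compare CD45.2 CD11cCre Cebpb knockout with CD45.1 wild-type macrophages in wild-type recipients, and ask what Cebpb does within the cell. Genotype is tied to donor and Cre. At 5 weeks (4 knockout, 3 wild-type libraries) the adaptor Ppfia4 rose to 60.4 ± 10.9 from 0.682 ± 0.213 CPM (6.43, SE 0.35), Retnla to 734 ± 331 from 66.2 ± 29.5 CPM and H2-Aa to 26300 ± 5800 from 11100 ± 3910 CPM. Car4 fell to 19.4 ± 11.9 from 393 ± 215 CPM (−4.34, SE 0.64, adjusted p 6.29e-04), the chitinase-like Chil1 to 2.02 ± 1.13 from 152 ± 101 CPM and Pparg to 18.8 ± 1.97 from 80.5 ± 25.9 CPM (−2.10, SE 0.35, 9.49e-04). Siglecf was not called (adjusted p 0.887). Lipid uptake, storage and PPAR target genes fell in 7 and rose in 2 of 20 cases (8 and 2 adjusted over the list alone; median −0.85, adjusted p 2.67e-04), with Lpl at −2.17 and Angptl4 at −3.25. MHC class II genes rose in 11 of 12 cases and fell in 0 (11 and 0 adjusted over the list alone; median 1.35), with adjusted p = 0.088 with an estimated correlation. Dendritic cell markers rose in 5 of 7 (7 adjusted over the list alone), with adjusted p = 0.14 with an estimated correlation. The 2509 genes called (1344 higher, 1165 lower) were 1480 without wild-type replicate 2 and 1392 without wild-type replicate 3.

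At 10 weeks (3 knockout, 4 wild-type libraries) Pparg fell to 29 ± 16.4 from 255 ± 55.7 CPM (−3.16, SE 0.39, adjusted p 2.47e-05), Krt79 to 6.45 ± 2.99 from 329 ± 41.1 CPM, Fabp1 to 5.38 ± 3.74 from 262 ± 62.8 CPM (−5.69, SE 0.45, 4.55e-07) and Siglecf to 13.3 ± 7.19 from 104 ± 19.6 CPM. C1qa rose to 5090 ± 1120 from 472 ± 347 CPM and the glycoprotein Gpnmb to 1610 ± 280 from 258 ± 46.2 CPM. Abca1 rose by 2.77 (SE 0.38). Cell cycle genes fell in 35 of 38 cases and rose in 0 (35 and 1 adjusted over the list alone; median −2.31, adjusted p 3.72e-15, or adjusted p = 0.0641 with an estimated correlation). Identity genes fell in 17 and rose in 1 of 26 (17 and 1 adjusted over the list alone; median −2.22), with adjusted p = 0.0641 with an estimated correlation. Lipid uptake, storage and PPAR target genes fell in 12 and rose in 4 of 20 (13 and 4 adjusted over the list alone; adjusted p 4.27e-04), with Cd36 (1.58, SE 0.34), Fabp5, Msr1 and Lipe higher. Inflammatory cytokines and chemokines rose in 17 and fell in 2 of 28 cases (17 and 2 adjusted over the list alone), with adjusted p = 0.114 with an estimated correlation. Dendritic cell markers rose in 4 of 7 cases, Flt3, Zbtb46, Cd209a and Clec10a (4 adjusted over the list alone; adjusted p 0.0247, or adjusted p = 0.328 with an estimated correlation), lymphocyte markers in 3 of 6 (4 adjusted over the list alone; adjusted p 0.183) and erythroid markers in 2 of 4, Hba-a1 and Hba-a2 (2 adjusted over the list alone; adjusted p 0.263). Mitochondrial counts took 0.42 to 0.9% of knockout and 0.15 to 0.19% of wild-type libraries. Genes passed in 5072 cases of 11136 (2723 higher, 2349 lower), fewer with a replicate block.

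The knockout effect differed between 10 and 5 weeks for 1508 genes (843 upward, 665 downward at 10 weeks). Lipid-associated macrophage genes differed upward in 8 of 14 cases and downward in 0 (8 and 0 adjusted over the list alone; adjusted p 2.16e-09), with Gpnmb at 2.42 (SE 0.30) and Trem2 at 2.21 (SE 0.28). Monocyte and tissue macrophage markers differed upward in 11 and downward in 0 (11 and 2 adjusted over the list alone), with Ms4a7 at 3.06 (SE 0.47). Siglecf (−3.08, SE 0.43), Krt79 (−4.32, SE 0.49) and Fabp1 (−4.66, SE 0.57) had lower fold changes at 10 weeks. Pparg did not differ by this test (−1.06, SE 0.50, adjusted p 0.179), with −0.62 without 10-week knockout replicate 2. The count was 906 without 5-week wild-type replicate 2 and 2918 without 10-week knockout replicate 1.

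Open chromatin was mapped by ATAC sequencing in cultured alveolar macrophages with MxCre, treated with IFNa and Csf2, without (n = 2) and with (n = 3) a floxed Cebpb. The deposited peak lists held 81880 and 92432 peaks in controls and 101952, 90597 and 88282 in knockouts, which merged to 129652 regions. Regions with a peak in both controls and no knockout numbered 4960 (3.83%), those with a peak in all 3 knockouts and no control 5627 (4.34%), and 52338 (40.4%) had a peak in all 5 libraries. At Cebpb the region from 167688898 to 167689305 on chromosome 2, inside the gene, had a peak in both controls and in 0 of 3 knockouts. The overlap of peak lists (Jaccard index) was 0.59 within controls, 0.599 to 0.611 within knockouts and 0.522 to 0.567 between them. In an exact permutation of the 5 labels the real split had the largest difference of 10, where the smallest share possible is 0.1. Without control replicate 1 or 2 the control-only regions numbered 12963 and 9167, and the knockout-only regions 8515 and 11465, with 8551 and 8931 without knockout replicates 2 and 3.

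C/EBPβ binding was mapped in wild-type alveolar macrophages by ChIPmentation, a chromatin immunoprecipitation with tagged libraries, in 2 replicates with 27105 and 22558 peaks. Of 29873 merged regions 18752 (62.8%) had a peak in both, and 80.1% of these lay on ATAC regions of both control cultures. A C/EBPβ region lay on 1120 of 4960 control-only ATAC regions (22.6%), on 77 of 5627 knockout-only regions (1.37%) and on 12983 of 52338 common regions (24.8%). The odds ratio of control-only against knockout-only regions was 21 (Fisher's exact test, two-sided, p 7.20e-297), where regions are not replicates and knockout-only regions have no peak in controls by definition, and it was 3.86 without control replicate 2. Against common regions the control-only odds ratio was 0.884 (p 4.94e-04) and 0.561 without control replicate 2. It was 1.1 with a −log10 q of at least 10 (p 0.011), so direction depends on the threshold. Width (median 338 against 617 bp) was not modelled.

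Genes lower in CD11b low Cebpb knockout cells had a C/EBPβ region within 10 kb of a gene end in 444 of 576 cases (77.1%). Genes not called had one in 4053 of 7195 cases (56.3%; odds ratio 2.61, Fisher's exact test, two-sided, p 1.62e-23), and higher genes in 373 of 699 (53.4%; 0.887, p 0.14). Under CD11cCre 72.5% of lower genes and 58.2% of higher genes had one, against 54.2% of the others (odds ratios 2.22, p 6.03e-20, and 1.18, p 0.0164). Within strata the shares were 62%, 52.1% and 51.4% (1.54, p 7.90e-19, and 1.03, p 0.555). With mean expression and gene length in a logistic model the odds ratios of lower genes were 2.48, 2.13 and 1.42 in the same order, and those of higher genes 0.798 (p 0.00534), 1.16 (p 0.0297) and 1.02 (p 0.621). The deficit near higher genes of CD11b low cells thus passed in the model alone.

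Pparg and 10 kb on either side held 26 ATAC regions, of which 14 had a peak in all 5 libraries, 0 were control-only and 1, from 115468013 to 115468314, was knockout-only. The same window held 17 C/EBPβ regions, 12 of them in both replicates, and the widest of these ran from 115420491 to 115422387. Lpl (chromosome 8, 68880555 to 68906932) and Cd36 (chromosome 5, 17781690 to 17888959) each had 3 C/EBPβ regions of both replicates, and Fabp1 (chromosome 6, 71199879 to 71205034) 2, Abca1 1 and Siglecf (chromosome 7, 43351341 to 43359475) 1. Fabp4 (chromosome 3, 10204342 to 10208616) had 0 in both replicates. Fabp4 and Cd36 each had 1 control-only ATAC region.

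**Figure D5:**
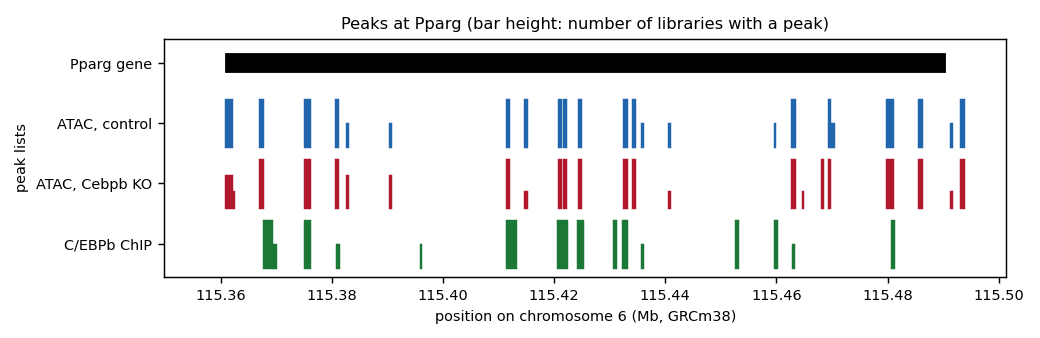
ATAC and C/EBPβ ChIP regions at Pparg (chromosome 6, position in Mb, GRCm38) in control and Cebpb knockout cultures and in wild-type macrophages, with bar height the number of libraries with a peak. Of 26 ATAC regions 14 have a peak in all 5 libraries, and 12 of 17 ChIP regions have one in both replicates.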

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

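The tests of library depth, dendritic cell transcripts, the spread of identity genes, mitochondrial counts, Y-linked libraries, peaks near the threshold, single control libraries and other splits of the samples were chosen after the results were seen, and the test of region width before.

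Some libraries stood apart from their own group. Siglecf, a lectin of alveolar macrophages, was 106 CPM in CD11b low knockout replicate 1 and 52.8 to 57.2 CPM in the other 3. Pparg was 555 CPM in E18 Csf2rb wild-type replicate 2 and 238 to 261 CPM in the others, and Cebpb 36.8 CPM in 5-week chimera knockout replicate 3 and 18.1 to 18.6 CPM in the others. Total counts were 12652229 in 10-week chimera wild-type replicate 1 (others 4078361 to 4832182), where 12813 genes were detected (others 11994 to 12079), and 2255774 in CD11cCre knockout replicate 4 (others 4062830 to 4188425). With 65 tests of this kind about 3 such values come by chance, at 1 in 20.

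Effects differed between groups for 840 genes between facilities, 1169 between males and females, 1508 between 10 and 5 weeks in the chimeras, 446 between Lip and Cebpb knockout, 1084 between E18 and adult Cebpb knockout and 1157 between Csf2rb and Cebpb knockout at E18. Irf7, Cidec, Gpnmb, Sqle, Fn1 and Plac8 are among the genes of these 6 contrasts, in this order.

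Splits of the same samples into other groups tested whether chance gives as many calls. Of 35 splits only the real one called as many genes for Cebpb knockout CD11b low (1286, highest other 1) and high (2044, 0). So it was for CD11b high against low (323, 18), CD11cCre (1677, 663), Lip CD11b low (2305, 666) and high (3505, 846). E18 Cebpb (2164, 3) and Csf2rb (2118, 0), Lip of the chromatin-matched set (469, 12) and Ly6Chi monocytes (334, 20) were alike. So were the chimeras at 5 (2509, 445) and 10 weeks (5072, 1832). At 1 of 35 each, uncorrected, chance is unlikely, not excluded. For the paired Lip CD11b high and low cells it was 1 of 35 as well (1742, 3), where splits that part all 4 pairs also called at most 3. Of 100 splits drawn, 1 reached the real value within strata (5018, highest other 3794). The same held for the chimera difference (1508, 435) and Csf2rb against Cebpb knockout (1157, 1040). For Lip against Cebpb knockout 2 of 100 reached 446 (highest other 659), and for the facilities 2 of all 60 reached 840 (1095). For males against females 3 of 100 reached 1169 (1999), and for E18 against adult knockout 3 of 100 reached 1084 (2566). In the last 4 contrasts another split called more genes than the real one. Where effects are compared, a difference between the sets can enter the splits, so chance stays open there. The Cebpb knockouts of the chromatin-matched set have 10 splits, too few for a share under 0.05 (2795, highest other 0).

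In CD11b low knockout cells identity genes such as Krt79 and Marco fell and MHC class II genes such as Cd74 rose. Replacement by cells without identity transcripts would lower them all alike, but their log2 fold changes had an SD of 2.12 (median SE 0.29). Cells with some of them stay open. Dendritic cells among the sorted cells may add to MHC class II, as the 8 marker genes rose by a log2 ratio of 1.93 ± 0.57 (SE) from 19 to 75 counts, led by Cd209a and Flt3, below the median of 4.33 of the MHC class II list. In knockout replicate 1 these genes held 3 counts (2.05 CPM) beside 5960 CPM of Cd74, but so few counts leave it open.

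The 10-week chimera, where Siglecf, Krt79 and Fabp1 fell further, called more genes than the 5-week one, less so with a replicate block. Depth did not account for it, since thinned libraries gave a ratio of 2.15 between the counts (5072 and 2509 genes without thinning). Nor did the libraries numbered 1, the only ones above 0.0815 CPM of Y-linked counts at 10 weeks, since without them 2699 genes differed between the times. Mitochondrial counts were 3.57 times higher in 10-week knockout than in wild-type libraries, so damaged cells could add to the difference and cannot be told apart from the effect of time. Time since transfer itself stays open.

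C/EBPβ lay more often on ATAC regions of control cultures only than on those of knockouts only (odds ratio 21). The width of the regions did not account for it (odds ratio 23.7, 95% interval 18.7 to 30, with width in the model), nor did peaks near the calling threshold (25.4 with a −log10 q of at least 10). Peaks of a single control library did not account for all of it, although the odds ratio was 3.86 without control replicate 2. Binding was mapped in wild-type cells, where 80.1% of C/EBPβ regions lay on ATAC regions of both controls, so a low share on knockout-only regions was largely set by their definition. Against common regions the direction depends on the threshold (odds ratio 0.884 or 1.1) and width was not modelled. Loss of open chromatin at bound regions stays open.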

How the results depend on the processing

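Tests chosen after the results were seen were those with thinned libraries, without the 10-week chimera libraries numbered 1, with crossed replicate numbers and with a −log10 q of at least 10. The other alternatives were fixed before the data were examined. Of 469 alternative values of counts and overlaps 380 stayed within 1.5 times, of 24807 of single genes 23511 kept their call and 0 reversed, and of 528 of gene lists 340 kept theirs. Scaling by DESeq2 size factors moved the share of higher genes by at most 5.04 percentage points and the median of all genes by at most 0.077. With these size factors 1273 of the 1286 genes of Cebpb knockout CD11b low cells were called with the same sign, and with the DESeq2 Wald test 1276. Its count was 968 to 1202 with each replicate left out, and 1072 with thinned libraries.

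An absolute log2 fold change of at least 1, a stricter threshold by construction, left 2072 of 5018 genes within strata, 3369 of 5253 in facility 2, 1471 of 2336 in knockout against heterozygous cells, 770 of 1677 under CD11cCre, 782 of 2305 in Lip CD11b low, 1265 of 3505 in Lip CD11b high and 440 of 1742 between these. It left 1845 of 2795 in the Cebpb knockouts of the chromatin-matched set, 206 of 334 in Ly6Chi monocytes, 1078 of 2509 and 2544 of 5072 in the chimeras at 5 and 10 weeks, and 986 of 1508 for their difference.

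Heterozygous cells gave 70 genes with edgeR, 226 with the DESeq2 Wald test and 176 without a count filter, and LyzMCre 405 and 805 without that filter. Thinned libraries gave 195 genes (323) between CD11b high and low knockout cells, 190 of them among the 323, where each library holds fewer counts by construction. With all samples of the count table in 1 fit, and so 1 shared estimate of the spread, the facility difference was 358 (from 840), that of males from females 514 (1169), CD11cCre 886 (1677), Lip CD11b low 824 (2305), Lip CD11b high 1745 (3505), their contrast 422 (1742) and the Lip difference from Cebpb knockout 236 (446). In that fit Csf2rb knockouts rose to 6008 (2118), their difference from Cebpb knockouts to 3256 (1157) and Ly6Chi monocytes to 566 (334). The cause was not tested.

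With the replicate number as a replicate block the counts were 1301 (from 2044) in CD11b high knockout cells, 1581 (2565), 2942 (5253) and 2272 (1201) in the strata of facility 1, facility 2 and males, 151 (70) in heterozygous cells, 2667 (1677) under CD11cCre, 946 (2118) with Csf2rb loss and 3049 (5072) in the 10-week chimera. The other blocked counts stayed within 1.5 times, and for the paired Lip CD11b high and low cells the block changed no call of a named gene. The labels give shared numbers and no pairs of samples, and outside Lip CD11b high and low cells correlations ran from −0.41 to 0.42. In the 10-week chimera all 3 pairs correlated best with their own number (r 0.09 to 0.16). Crossed numbers in groups of 2 gave 747 genes (405) for LyzMCre and 2491 (2565) for facility 1.

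Leaving out 1 replicate moved the counts below by more than 1.5 times. CD11b high against low knockout cells ranged from 152 (without low replicate 1) to 371 (without high replicate 3), facility 1 from 1401 (without knockout replicate 2) to 2205 (without knockout replicate 1), and males from 519 (without wild-type replicate 2) to 731 (without knockout replicate 1). Heterozygous cells ranged from 23 (without wild-type replicate 2) to 69 (without heterozygous replicate 1), and knockout against heterozygous cells from 1099 (without knockout replicate 2) to 2160 (without heterozygous replicate 1). The facility difference ranged from 273 (without facility 1 knockout replicate 1) to 1742 (without facility 2 knockout replicate 1), and that of males from females from 334 (without male wild-type replicate 2) to 1931 (without facility 2 knockout replicate 1). Where 1 sample stayed in an arm, its spread was taken to be that of the other groups.

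LyzMCre ranged from 214 (without wild-type replicate 1) to 2747 (without knockout replicate 2), CD11cCre from 1095 (without control replicate 1) to 2688 (without knockout replicate 4) and Csf2rb loss from 1325 (without wild-type replicate 4) to 2809 (without knockout replicate 2). Ly6Chi monocytes ranged from 114 (without wild-type replicate 2) to 368 (without knockout replicate 3), the 5-week chimera from 1392 (without wild-type replicate 3) to 2232 (without knockout replicate 1) and the Csf2rb difference from Cebpb knockouts from 749 (without Cebpb wild-type replicate 1) to 1871 (without Csf2rb knockout replicate 2). The difference between 10 and 5 weeks ranged from 906 (without 5-week wild-type replicate 2) to 2918 (without 10-week knockout replicate 1), and was 2699 without both 10-week libraries numbered 1. The cause was not tested.

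In the ATAC lists control-only regions ranged from 5712 (without knockout replicate 3) to 12963 (without control replicate 1), and knockout-only regions from 6859 (without knockout replicate 1) to 11465 (without control replicate 2). Fewer libraries ask for fewer peaks by construction, so these counts can only rise. A −log10 q of at least 10, which removes peaks by construction, gave 2110 knockout-only regions (5627) and 11585 C/EBPβ regions of both replicates (18752), sorted anew from the remaining peaks. The odds ratio of C/EBPβ on control-only against knockout-only regions ran from 3.86 (without control replicate 2) to 17.6 (without knockout replicate 3), and was 32.2 with an overlap of 50%. Odds ratios of C/EBPβ near lower genes were 1.54 to 3.03 over the peak thresholds, overlaps and distances run, and 1.42 within strata with expression and gene length in a model. Corrections for GC content were not run.

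The smallest library holds 642269 counts. Of simulated 2-fold changes 65.7% were found in CD11b low cells (4 against 4) and 19.4% in LyzMCre (2 against 2). A list call that held with the preset correlation and was lost with an estimated one stays open.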

Other observations

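The comparisons of genes near C/EBPβ and ATAC regions for genes lower in all 3 deletions were tests chosen after the results were seen, while the genes of this paragraph are among the largest changes under a rule fixed before. In the 10-week chimera the interleukin 7 receptor Il7r rose in knockout cells (4.78, SE 0.31, adjusted p 3.71e-08). Galanin, Gal, fell by 5.88 (SE 0.49) and the secreted Wfdc21 fell by 6.12 (SE 0.56). In the 5-week chimera Wfdc21 (−4.39, SE 0.46), the protease Ctse (−4.43, SE 0.36) and the sialic acid lyase Npl (−4.21, SE 0.35) fell. Ctse went the other way in adult knockouts within strata (4.57, SE 0.34).

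Lysosome and surfactant breakdown genes fell in 12 of 24 cases and rose in 0 in the 5-week chimera (12 and 0 adjusted over the list alone; median −0.44, camera adjusted p 8.37e-06, or adjusted p = 0.131 with an estimated correlation). GM-CSF receptor and STAT5 target genes rose in 8 of 14 and fell in 1, Osm (11 and 1 adjusted over the list alone; adjusted p 2.62e-04, or adjusted p = 0.088 with an estimated correlation). Stress and dissociation genes rose in 9 of 13 in E18 Cebpb knockouts (10 adjusted over the list alone; adjusted p 4.31e-06, or adjusted p = 0.0571 with an estimated correlation).

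Genes lower in all 3 Cebpb deletions, a set with Krt79, Car4 and Marco, may more often be direct targets of C/EBPβ, since 204 of 246 (82.9%) had a C/EBPβ region of both replicates within 10 kb against 228 of 406 genes higher in all 3 (56.2%; odds ratio 3.79, Fisher's exact test, two-sided, p 7.79e-13). An ATAC region of control cultures only lay near 63 of the lower genes (25.6%) and 66 of the higher ones (16.3%; odds ratio 1.77, p 0.00446), and a region of knockout cultures only near 12.2% and 15.8% (0.742, p 0.25). The set of higher genes, with Mmp12 and Csf1, lay near C/EBPβ regions about as often as the genes not shared by all 3 deletions in 1 direction (57.2%), which suggests that their rise need not involve binding within 10 kb. The ATAC regions come from cultures with IFNa and Csf2, genes are not replicates, and binding at each gene named here was not looked up.

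Y-linked transcripts marked 10-week chimera knockout replicate 1 (55 CPM) and wild-type replicate 1 (37.1 CPM), and Ly6Chi and E18 premature macrophage groups mixed libraries with high and low levels, unevenly for Csf2rb (high in 1 of 4 wild-type and 2 of 3 knockout libraries).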
